A study of Homo sapiens with 8 samples.

How the data were processed

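Expression was measured in total RNA extracted with a mirVana kit and labelled with biotin, per the labels' protocols, from cells grown in DMEM with serum. The 8 samples were grouped by their titles into MDA-MB-231, LM2, LM2 control and LM2 with miR-126, 2 arrays each, called A and B after the letters in the titles. Abbreviations in the titles that the labels do not explain were left unread.

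The authors deposited 1 table of processed intensity values per platform, and the software and normalization behind them are not given in the sources used here. The deposited Illumina intensities were linear, with the same median of 94.39 on each array and lowest values between 43.21 and 46.47, so the background was not fully subtracted and the folds of dim genes are understated. The deposited Affymetrix intensities were linear and relative to each array's own median, which was 1. No scanner files and no detection p-values were used here, so no level was called absent and no bound on a fold is given. The precision is limited by the number of arrays.

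Probes were named through the platform annotation and updated by Entrez identifiers. Of 48803 Illumina probes, 28098 had 1 gene symbol, 13 several and 20692 none, and 28059 matched by identifier. Of 54675 Affymetrix probe sets, 62 were controls, 41091 had 1 symbol, 1801 several and 11721 none, and 41037 matched by identifier. Control probes and probes with no gene or several genes were left out. The probe with the highest mean over the 4 arrays stood for a gene (18852 and 19775 genes), and genes with a mean above the median of all probes' means were tested (12490 and 12923).

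The design fixed before the data were examined had assumed linear intensities well above 1, to be set to at least 1 and taken as log2(value + 16). This was done for the Illumina table, which stayed on its deposited scale because its quartiles differed by 0.0493 log2, under the limit of 0.1. It could not be kept for the Affymetrix table, whose median is 1 and where it would have flattened most genes, so log2 of the value with no pseudocount was used, and the assumed form was run as an alternative. Quantile normalization was applied there because the quartiles differed by 0.164 log2. Illumina fold changes are on the log2(value + 16) scale, which also understates changes of dim genes.

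Groups were compared within each table with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot give a p under 0.3333, so the tests rest on the spread that limma shares across genes. Of 31 gene lists fixed before the data were examined, 26 had at least 5 genes above the filter in each table, 25 of them the same in both, with the fibroblast list tested on the Illumina and the endothelial list on the Affymetrix arrays. They were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. With an estimated correlation, camera also rests on the 2 residual degrees of freedom of each table. A loss in that setting therefore need not come from correlation between genes. It may, however, since the estimate lay above 0.01 for most lists that passed. The lists cover genes linked to miR-126 or to this metastatic line, stress and signalling pathways, and markers of cell types. Overlap between comparisons was tested with Fisher's exact test. Differences between arrays of a group were set against 10000 random lists matched on size and on 20 bins of expression. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

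Genes named in the text were those with the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, or, where fewer than 5 passed, the 5 of smallest p in that direction. A fixed set linked to miR-126 and to metastasis of these cells was always named, as were up to 4 called members of smallest p per list and genes past the threshold in both comparisons. Genes named outside this rule are said to be chosen after their values were seen.

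The steps were tested on simulated data made from each table's own means and spread. Over 12490 genes, the Illumina setting recovered 81 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 8 false calls. Over 12923 genes, the Affymetrix setting recovered 35 and 96 of 100, with 7 false calls. Of 100 lists with no change, 2 and 0 had a camera p under 0.05.

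The alternatives covered the scaling, the pseudocount, the filter, the probe rule, the variance prior, the set test, the replicate letter as a block, a fold minimum of 1.5 and each array left out in turn. Cyclic loess, the assumed log form on the Affymetrix table and the overlap without amino acid stress genes were added after the data were seen. A planned test of genes with miR-126 sites in their 3' untranslated regions was not run, since no sequences were given. No genome build is named in the sources used here, so no coordinates are printed.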

Results

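Total RNA from human breast cancer cells was profiled on 8 expression arrays, 2 for each of 4 groups. MDA-MB-231, a poorly metastatic triple-negative breast cancer line, and LM2, a derivative of it that metastasises to the lung, were measured on Illumina bead arrays. LM2 cells over-expressing the microRNA miR-126 and LM2 control cells were measured on Affymetrix arrays. The platforms shared no array or control, so each comparison was made within its own table, over 12490 genes on the Illumina arrays and 12923 genes on the Affymetrix arrays. The number of arrays limits the precision, and the labels do not say whether arrays A and B of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The mature microRNA was not measured on either platform, so its level could not be checked. EGFL7, the gene that hosts miR-126 in an intron, differed between miR-126 cells and control cells by -0.12 log2 (adjusted p = 0.864) and lay below the expression filter on the Illumina arrays.

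The arrays of a group differed by different amounts. Averaged over genes, the absolute difference was 0.248 log2 between the MDA-MB-231 arrays and 0.188 log2 between the LM2 arrays, against 0.229 log2 between the means of these groups. It was 0.087 log2 between the LM2 control arrays but 0.284 log2 between the miR-126 arrays, which was more than the 0.159 log2 between the means of control and miR-126 cells.

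The first comparison asked how the transcripts of the metastatic derivative LM2 differed from those of MDA-MB-231. LM2 cells expressed more of the matrix glycoprotein SPARC, the decoy cytokine receptor IL13RA2, the inflammatory cytokine IL1B and the collagen chain COL6A1. They expressed less of CEMIP, which takes part in hyaluronan breakdown, of the extracellular matrix proteins EFEMP1 and MATN2, of the death ligand TNFSF10 and of ID3, an inhibitor of helix-loop-helix transcription factors. SPARC was 7.35-fold higher, with log2 levels of 6.57 ± 0.22 in MDA-MB-231 and 9.45 ± 0.48 in LM2 (SD, n = 2 each). Its level in MDA-MB-231 lay below the median of all probes (6.79), where background that was not subtracted makes up part of the signal, so this fold understates the change. CEMIP was 13.4-fold lower, with log2 levels of 10.97 ± 1.1 and 7.23 ± 0.015, the latter near the upper quartile of all probes (7.17).

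With limma, 105 genes were higher and 184 lower in LM2 at an adjusted p under 0.05. The largest rises were in WDR72 (log2 change 3.22, SE 0.23, adjusted p = 0.000116), PHGDH (2.89, SE 0.62, adjusted p = 0.0383), SPARC (2.88, SE 0.24, adjusted p = 0.000271) and IL13RA2 (2.85, SE 0.25, adjusted p = 0.000454). MAGEB2, APOBEC3G, IL1B, CHRM3, MT1X and COL6A1 followed, with log2 changes from 2.75 for MAGEB2 to 2.09 for COL6A1. The largest falls were in CEMIP (-3.74, SE 0.38, adjusted p = 0.000866), EFEMP1 (-3.45, SE 0.26, adjusted p = 0.00013) and RARRES2, which encodes the chemoattractant chemerin (-2.82, SE 0.20, adjusted p = 0.000116). C4BPB, PLAAT4, MATN2, TNFSF10, HCP5, IFI27 and ID3 followed, from -2.66 for C4BPB to -2.26 for ID3. In 7 of these 20 genes the dimmer group lay below the upper quartile of all probes, MDA-MB-231 for WDR72 (6.85), SPARC (6.57), IL13RA2 (6.55), MAGEB2 (6.90) and CHRM3 (6.90), and LM2 for RARRES2 (6.91) and C4BPB (7.03). Their changes are understated, and their order against the other genes is not settled. The dimmer group also lay there for 9 genes with smaller changes, PTPRN2, PLK2, CADM1, CSF3, CDH1, CCL2, ANGPTL4, COL1A1 and NUPR1. PHGDH, the first enzyme of serine synthesis, stood at log2 levels of 8.01 and 10.70 on the MDA-MB-231 arrays A and B, and its rise was 1.55 without array A. MT1X stood at 9.02 and 11.03 on these arrays, and its rise was 1.27 without array A. MAGEB2 and the metallothionein gene MT1X belong to families of close paralogs, whose transcripts their probes may share. The other probe, below the filter, stood at -0.03 for WDR72, -0.10 for CHRM3 and 0.11 for MAGEB2. That of MATN2, above the filter, stood at -0.54. Over the settings the smallest changes were 1.59 for WDR72, 1.12 for CHRM3, 1.43 for MAGEB2 and -1.58 for MATN2. The counts were 294 and 397 without MDA-MB-231 array B, 46 and 40 without LM2 array A, and 76 and 40 without LM2 array B, and quantile normalization gave 131 higher and 131 lower genes, which moved the higher share of calls from 36.3% to 50%. The mean of a gene's probes gave 66 and 118 genes, and a variance prior without a trend 41 and 66. The calls of PHGDH and MT1X were lost when either LM2 array was left out, with the mean of a gene's probes, with a robust variance prior and with a prior without a trend. That of PHGDH was also lost under quantile normalization and that of MT1X under a filter at the 75th percentile. PHGDH and MT1X have 1 probe each, so with the mean of probes their own values did not change. ID3 lost its call without LM2 array A and under both other priors, and TNFSF10 and IFI27 lost theirs under the prior without a trend.

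**Figure D1:**
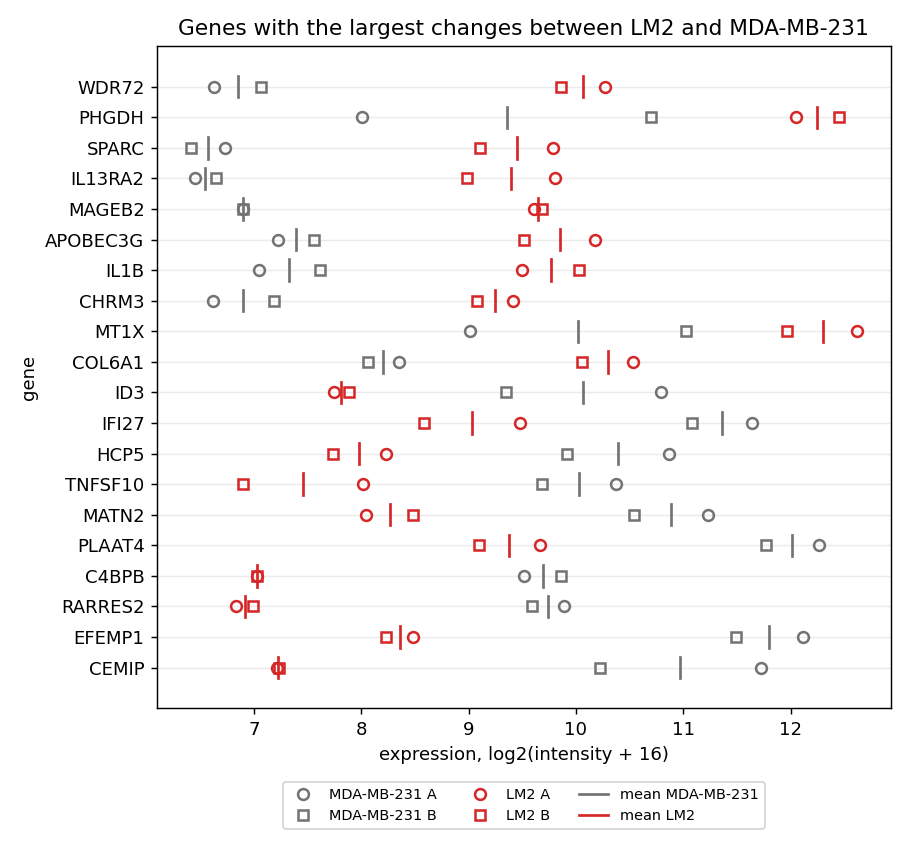
Expression of the 20 genes with the largest changes between LM2 and MDA-MB-231, as log2(intensity + 16) on each array (circles: array A; squares: array B; vertical bars: group means). The genes were chosen so that both LM2 arrays lie on one side of both MDA-MB-231 arrays. The MDA-MB-231 arrays lie far apart for PHGDH, at 8.01 and 10.70.

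Gene lists fixed before the data were examined were then compared between the lines. Genes known from earlier work to be higher in lung-metastatic derivatives of this line were higher in LM2. LM2 is itself such a derivative, so this rise was fixed in part by how the list was chosen. Of 15 measured, 7 rose and none fell, with a median log2 change of 1.13, and 11 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.71e-11, and adjusted p = 0.523 with an estimated correlation). Besides SPARC and IL13RA2, the kynureninase gene KYNU (1.99), the lipoprotein lipase inhibitor ANGPTL4 (1.79), the prostaglandin synthase PTGS2 (1.43) and the matrix protein TNC (1.04) rose. The other ANGPTL4 probes, below the filter, stood at 0.13 and -0.15, and its smallest change over the settings was 0.59. PTGS2 was at 0.94 without LM2 array A. Genes of the amino acid stress response driven by the transcription factor ATF4 were also higher, with a median of 0.28; 5 of 20 rose, 7 when adjusted over the list alone (camera adjusted p = 6.62e-07, and adjusted p = 0.523 with an estimated correlation). The median was 0.76 without MDA-MB-231 array A and 0.22 without array B. The genes past the threshold over all genes were PHGDH, PSAT1 (1.30) and SHMT2 (1.17), enzymes of serine and glycine synthesis, and the transcriptional regulators CEBPB (1.18) and NUPR1 (0.82). Matrix genes (median 0.17, camera adjusted p = 0.000454, and adjusted p = 0.693 with an estimated correlation) had 4 of 26 members higher, SPARC, COL6A1, COL1A1 (1.94) and TNC, and THBS1, which encodes thrombospondin, lower at -1.57; adjusted over the list alone, 10 rose and 4 fell. NF-kB inflammatory genes had a median of 0.11 (camera adjusted p = 0.0102, and adjusted p = 0.693 with an estimated correlation). Of 19, 3 were higher, IL1B, CSF3 (1.34) and PTGS2, and the chemokine CCL2 was lower at -0.78. Adjusted over the list alone, 6 rose and 2 fell. The other CSF3 probes, below the filter, stood at 0.13 and 0.37, and its smallest change over the settings was 0.61. MAPK output genes (median 0.24, camera adjusted p = 0.00161, and adjusted p = 0.799 with an estimated correlation) had 1 of 19 higher, the feedback inhibitor SPRY4 (1.23), for which 3 of 4 probes had this sign, and also 1 when adjusted over the list alone.

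Antigen presentation genes were lower in LM2, with a median of -0.77 (camera adjusted p = 6.62e-07, and adjusted p = 0.523 with an estimated correlation). The peptide transporter TAP1 (-1.41) and the immunoproteasome subunits PSMB8 (-1.0) and PSMB9 (-0.92) fell, 3 of 12 genes measured, and 9 fell when adjusted over the list alone. Of 24 interferon response genes, IFI27 (-2.33), IFIT1 (-1.42), IFIT2 (-1.12) and MX1 (-1.10) fell and none rose, with a list median of -0.22 and 8 lower when adjusted over the list alone (camera adjusted p = 0.0133, and adjusted p = 0.523 with an estimated correlation). CDH1, the epithelial cadherin, fell by 0.54, as 1 of 14 genes of the epithelial state (list median -0.34, camera adjusted p = 0.00146, and adjusted p = 0.771 with an estimated correlation). It was also the 1 gene called of 7 luminal epithelial markers (list median -0.54, camera adjusted p = 0.00385, and adjusted p = 0.523 with an estimated correlation). Adjusted over the list alone, 7 epithelial genes and 5 luminal markers fell. The MDA-MB-231 arrays themselves differed over some of these lists, array A above array B by a median of 0.39 for epithelial, 0.23 for antigen presentation, 0.22 for amino acid stress and 0.12 for matrix genes. LM2 array A lay above array B by 0.46 for MAPK output, 0.41 for lung metastasis, 0.32 for matrix and 0.24 for NF-kB genes, and each of these differences lay outside the 95% range of random lists. Without MDA-MB-231 array B the camera adjusted p was 0.0663 for the interferon list, 0.0663 for the matrix list and 0.118 for the NF-kB list. Without MDA-MB-231 array A it was 0.125 for the epithelial list, and without LM2 array A it was 0.233 for the MAPK list. Without MDA-MB-231 array A or B the median was -0.18 or -0.53 for the epithelial, 0.19 or 0.003 for the NF-kB and 0.13 or 0.38 for the MAPK list. Without LM2 array A or B it was -0.058 or 0.19 for the NF-kB and -0.043 or 0.42 for the MAPK list, and 0.10 without LM2 array A for the matrix list. No filter gave medians of -0.086 for the epithelial, -0.28 for the luminal and 0.060 for the matrix list, and the mean of all probes gave 0.71 for the lung metastasis list. A filter at the 75th percentile gave an adjusted p of 0.0596 for the epithelial and 0.0533 for the luminal list, and medians of -0.75 for the epithelial, -0.36 for the interferon and 0.34 for the matrix list. Quantile normalization gave a median of 0.37 for the MAPK list. Among the members named, CEBPB, PSAT1, SHMT2, TNC, THBS1, SPRY4, CCL2, TAP1, PSMB8, PSMB9, IFIT2, MX1 and CDH1 lost their calls when either LM2 array was left out, and KYNU, PTGS2, NUPR1 and IFIT1 without LM2 array A. PSAT1, SHMT2, TNC, THBS1, IFIT2 and CDH1 also lost theirs without MDA-MB-231 array A, THBS1 and PSMB8 under quantile normalization, and IFIT2 and PSMB8 without a filter. The mean of a gene's probes ended the calls of CEBPB, PSAT1, SHMT2, TNC, THBS1, SPRY4, CCL2, PSMB8, PSMB9, IFIT2 and PTGS2. A variance prior without a trend ended those of PSAT1, SHMT2, TNC, THBS1, SPRY4, CCL2, PSMB9, IFIT2, CDH1, KYNU, PTGS2 and NUPR1. CEBPB, SHMT2, THBS1, CCL2 and IFIT2 have 1 probe each. With the mean of probes their own values did not change, only what the test shares across genes.

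The other 17 lists of enough genes had camera adjusted p from 0.0555 to 0.92. With an array left out some of them passed, the hypoxia, glycolysis, cholesterol synthesis and TGF-beta lists without MDA-MB-231 array A, and the mitosis and ribosomal protein lists without MDA-MB-231 array B. YAP/TEAD targets passed without LM2 array A, and the hypoxia and mitosis lists without LM2 array B. Among their members, the cell adhesion gene CADM1 (1.79) and PLK2 (-0.68) passed in opposite directions in a list of miR-126 targets published from other cells (1 of 19 higher and 1 lower, 3 and 2 when adjusted over the list alone; camera adjusted p = 0.121). The glycolytic aldolase ALDOC rose (1.57), and GAS6 (-1.67, with 3 of 4 probes of this sign), the ephrin EFNA1 (-0.80), tissue factor F3 (-1.44) and TGFB2 (-0.98) fell. Of these calls, PLK2, EFNA1 and TGFB2 were lost when either LM2 array was left out, ALDOC and F3 without LM2 array A and GAS6 without LM2 array B, and each of these 6 under a variance prior without a trend. The mean of a gene's probes ended those of PLK2 and EFNA1, though PLK2 has 1 probe, whose own values did not change. Median, mean and test differed in sign for the mesenchymal, IGF axis, unfolded protein, TGF-beta and fibroblast lists. Of markers of other cell types, 1 of 7 fibroblast markers, the collagen chain COL1A1, was called (camera adjusted p = 0.492). None of 4 endothelial markers, 4 blood cell markers or 1 melanocyte marker above the filter was called, and these lists were too short for a test.

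Genes linked to miR-126 or to lung metastasis of these cells were followed whatever their result. IGFBP2, an IGF-binding protein, PITPNC1, a phosphatidylinositol transfer protein, and the receptor tyrosine kinase MERTK are known from the study itself, so the list is not independent evidence of its direction. None of these passed in LM2 against MDA-MB-231. The log2 change was 0.54 for IGFBP2 (SE 0.16, adjusted p = 0.125), 0.70 for PITPNC1 (SE 0.18, adjusted p = 0.088) and 0.21 for MERTK (SE 0.25, adjusted p = 0.776), whose other probe had a change of -0.05; adjusted over the list alone, IGFBP2 and PITPNC1 passed. IGFBP2 stood at log2 levels of 6.55 in MDA-MB-231 and 7.09 in LM2. Both lay below the upper quartile of all probes (7.17), so its change is understated. The changes of IGFBP2, PITPNC1 and MERTK each depended on single arrays. IGFBP2 was at 0.25 without LM2 array A and at 0.83 (adjusted p = 0.0107) without LM2 array B, PITPNC1 at 0.90 (adjusted p = 0.0122) without MDA-MB-231 array B, and MERTK at -0.12 and 0.55 without MDA-MB-231 array A and B and at 0.10 and 0.32 without LM2 array A and B. Of the genes linked to miR-335 in LM2, PTPRN2 (0.94, adjusted p = 0.00842) and TNC (1.04, adjusted p = 0.034) rose, 2 of 4, and 3 when adjusted over the list alone, while SOX4 stood at 0.40 (adjusted p = 0.297), and at 0.20 without LM2 array A. TNC lost its call when either LM2 array or MDA-MB-231 array A was left out and with the mean of its probes, and PTPRN2 and TNC lost theirs under a variance prior without a trend. VCAM1 (1.44, adjusted p = 0.148), MMP1 (0.63, adjusted p = 0.175) and SPRED1 (0.03, adjusted p = 0.977) did not pass, and SPRED1 had no stable sign, at -0.01 without MDA-MB-231 array B and -0.20 without LM2 array A. VCAM1 was at 0.91 and 1.97 without MDA-MB-231 array A and B and at 0.66 and 2.22 without LM2 array A and B, with an adjusted p of 0.0213 without MDA-MB-231 array B and 0.0193 without LM2 array B. MMP1 was at 0.38 without MDA-MB-231 array A and at 0.89 (adjusted p = 0.0238) without array B. PIK3R2 and CRK were not analysed here.

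The second comparison asked which transcripts differ when miR-126 is over-expressed in LM2. Against control cells, the amino acid stress genes stood lower on both miR-126 arrays, among them the asparagine synthetase ASNS at -1.24 log2 and the stress transcription factor DDIT3 at -1.14. Cholesterol synthesis genes and unfolded protein response genes also stood lower as lists. With an estimated correlation the adjusted p was 0.269 for the amino acid stress list and 0.773 for each of the others. ID3 stood 5.41-fold higher, at log2 levels of 0.29 ± 0.35 in control cells and 2.73 ± 0.21 in miR-126 cells relative to the array median (SD, n = 2 each). No gene passed the threshold for single genes.

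With limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.446. At an unadjusted p under 0.05, 436 genes were higher and 572 lower, 1008 in all, where 646 would be expected by chance. A variance prior without a trend, a robust prior and each of the 3 scalings also gave 0 genes. With 200 changed genes planted in simulated data, 96 of 100 were found at 4-fold and 35 of 100 at 2-fold. In the data ID3, at 5.41-fold, did not pass. These shares therefore do not say how large a change could have been missed here. Leaving out a miR-126 array takes the spread from the controls alone and gave 2275 higher and 2321 lower genes without array A, and 2549 and 2222 without array B. The genes of smallest p that stood higher, none past the threshold, were ID3 (log2 change 2.44, SE 0.22, adjusted p = 0.446), the growth factor homologue FGF13 (1.41, SE 0.13), the antisense transcript TPT1-AS1 (0.95, SE 0.09), FUBP3 (0.82, SE 0.10) and the urocortin gene UCN2 (0.86, SE 0.12). In control cells ID3 (0.29), FGF13 (-0.21), TPT1-AS1 (-0.005) and UCN2 (0.01) stood close to the array median in log2, so they were dim there. The other FUBP3 probe set above the filter stood at -0.18. Those that stood lower were ASNS (-1.24, SE 0.12, adjusted p = 0.446), PEBP1, an inhibitor of RAF kinase (-0.70, SE 0.07), DDIT3 (-1.14, SE 0.12), RBCK1 (-0.89, SE 0.10) and the protease inhibitor CST6 (-1.0, SE 0.12).

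The genes the study links to miR-126 stood lower in miR-126 cells without passing over all genes, and the list is again not independent evidence. IGFBP2 stood at 1.55 ± 0.034 in control cells and 0.65 ± 0.42 in miR-126 cells (log2, SD, n = 2 each). Its change was -0.90 (SE 0.22, adjusted p = 0.486), that of MERTK -0.64 (SE 0.13, adjusted p = 0.483) and that of PITPNC1 -0.30 (SE 0.15, adjusted p = 0.692). Without miR-126 array A the change was -0.60 for IGFBP2 and -0.16 for PITPNC1, and without array B it was -1.20 and -0.44. IGFBP2 and MERTK passed when adjusted over the list alone, and the 4 PITPNC1 probe sets above the filter were all lower. Besides the one reported, they stood at -0.22, -0.22 and -1.04 (SE 0.25), so the size of the PITPNC1 change depends on the probe set. The published targets from other cells did not stand apart, with 8 of 18 higher and 10 lower, none past the threshold over all genes or over the list alone, and a median of -0.01 (camera adjusted p = 0.687). Among them SPRED1 stood at -0.22 (SE 0.22, adjusted p = 0.831) and VCAM1 at 0.44 (SE 0.64, adjusted p = 0.898). SOX4 (-0.47), TNC (0.38), PTPRN2 (-0.09), MMP1 (0.25), ANGPTL4 (-0.32) and PTGS2 (0.53) had adjusted p of 0.647 or more. Without miR-126 array A the sign turned for SPRED1, SOX4, PTPRN2, MMP1 and ANGPTL4, to 0.06, 0.54, 0.15, -0.64 and 0.11, and without array B for VCAM1, PTGS2 and EGFL7, to -0.56, -0.04 and 0.02. With the other miR-126 array left out instead, the changes were -0.50, -1.49, -0.33, 1.14 and -0.75 for the former genes and 1.44, 1.10 and -0.25 for the latter. TNC was at 0.18 without array A and 0.58 without array B, and turned to -0.072 with the mean of its 3 probe sets, of which 1 that lay below the filter stood at -0.61 (SE 0.17).

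Among the lists, the amino acid stress genes had the smallest p. Of 21 measured, 20 stood lower, with a median log2 change of -0.66, and 14 were lower when adjusted over the list alone (camera adjusted p = 1.6e-17, and adjusted p = 0.269 with an estimated correlation). The median was -0.65 on miR-126 array A and -0.88 on array B. It was -0.29 with a floor of 1 and log2(value + 16) and -0.10 with log2(value + 64), forms that shrink changes where the array median is 1, and the list passed in 15 of 15 settings other than the set tests. With fry, which asks only whether the genes move one way on balance, the adjusted p was 0.0432. Chosen after their values were seen, NUPR1 (-1.55, SE 0.20), the cysteine-forming enzyme CTH (-1.24, SE 0.16), the amino acid transporter SLC7A5 (-1.04, SE 0.27), ATF3 (-1.0, SE 0.14), TRIB3 (-0.91, SE 0.11) and PHGDH (-0.69, SE 0.13) were members that stood lower, and ATF4 itself stood at -0.34 (SE 0.08).

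Of 18 cholesterol synthesis genes, 16 stood lower, with a median of -0.44 and 5 lower when adjusted over the list alone (camera adjusted p = 1.63e-07, and adjusted p = 0.773 with an estimated correlation). The median was -0.71 on array A and -0.18 on array B, and FDPS (-0.61) and SQLE (-0.71), chosen after their values were seen, are enzymes of the pathway. Of 16 unfolded protein response genes, 14 stood lower, with a median of -0.20 and 6 lower when adjusted over the list alone (camera adjusted p = 6.52e-06, and adjusted p = 0.773 with an estimated correlation). The median was -0.42 on array A and -0.10 on array B, and -0.12 with the mean of all probes. Chosen in the same way, the chaperone HSPA5 stood at -0.71 and HERPUD1 at -1.28. These lists and the amino acid stress list passed when either miR-126 array was left out, unlike the remaining 4. Such fits take their spread from the controls alone, and the hypoxia list also passed both ways, with medians of opposite sign. Passing both ways is therefore weak evidence for a list. MAPK output genes (13 of 19 lower, median -0.18, 2 lower when adjusted over the list alone, camera adjusted p = 0.00993, and adjusted p = 0.773 with an estimated correlation) and epithelial genes (11 of 15 lower, median -0.23, none when adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.773 with an estimated correlation) had adjusted p of 0.96 and 0.245 without array A, with medians of 0.034 and -0.030, and the mean of all probes gave 0.0624 for the epithelial list. DNA replication genes stood higher (18 of 20, median 0.21, none when adjusted over the list alone, camera adjusted p = 0.000394, and adjusted p = 0.773 with an estimated correlation), with medians of 0.45 on array A and 0.05 on array B and an adjusted p of 0.96 without array A. NF-kB inflammatory genes stood higher (18 of 21, median 0.27, none when adjusted over the list alone, camera adjusted p = 0.0137, and adjusted p = 0.79 with an estimated correlation), with medians of -0.10 and 0.68 and an adjusted p of 0.458 without array B. With log2(value + 64) the medians of these 6 lists also shrank, to between -0.056 for cholesterol synthesis and 0.040 for DNA replication, and each passed.

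**Figure D2:**
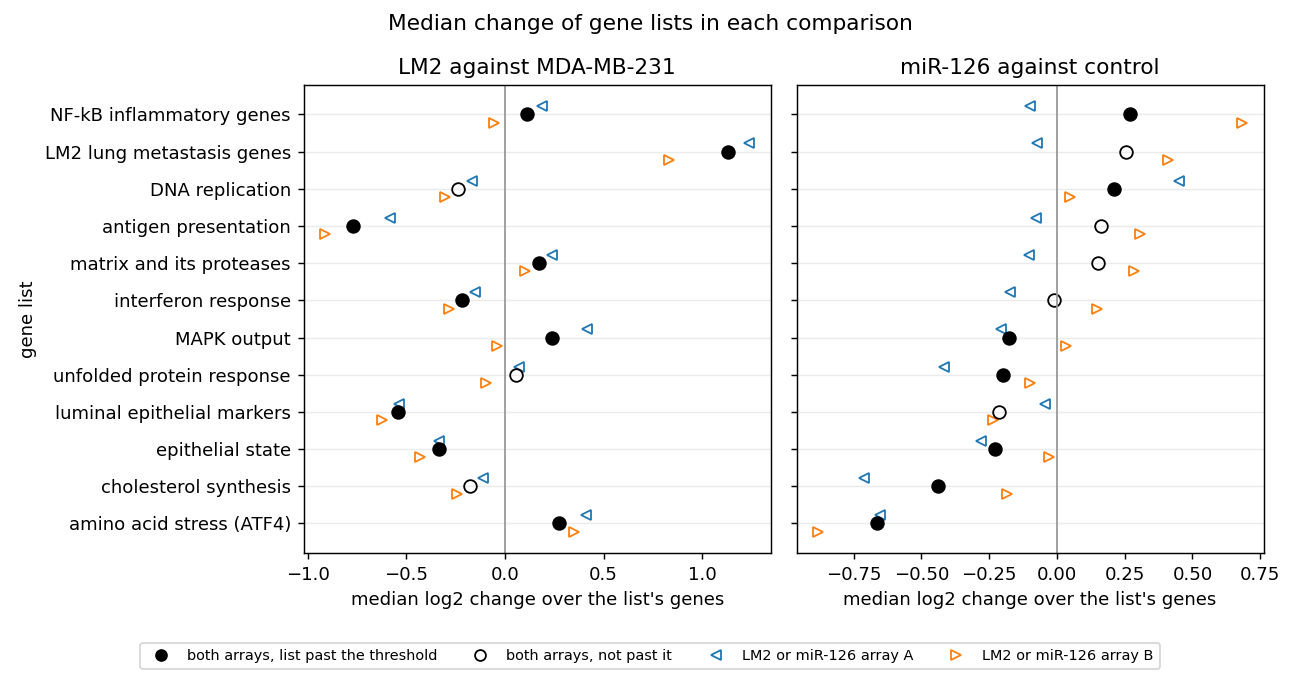
Median log2 change over the genes of the 12 lists past the threshold in at least 1 comparison, for LM2 against MDA-MB-231 (left) and miR-126 against control (right). Circles give the change between group means (filled: camera adjusted p under 0.05), and triangles give array A (left-pointing) and array B (right-pointing) of the LM2 or miR-126 group against the mean of the other group; the amino acid stress list lies at 0.28 on the left and at -0.66 on the right.

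The remaining 19 lists of enough genes had camera adjusted p from 0.0748, for the lung metastasis genes (median 0.25), to 0.972. The lung metastasis list passed without miR-126 array A (median 0.41, adjusted p = 1.82e-08), and its median was -0.074 without array B. It also passed without control array A (adjusted p = 0.00725) or B (adjusted p = 0.000438). Of the 19 lists, 10 passed without miR-126 array A, 9 without array B, 2 without control array A and 4 without control array B. The hypoxia, glycolysis, interferon and secreted angiogenic lists passed without either miR-126 array, with medians of opposite sign. Median, mean and test differed in sign for the hypoxia, glycolysis, oxidative phosphorylation, interferon, secreted angiogenic and IGF axis lists. Endothelial markers (5 genes, median -0.22, camera adjusted p = 0.139) and luminal markers (7 genes, median -0.21, camera adjusted p = 0.217) did not pass, and 3 blood cell, 4 fibroblast and 3 melanocyte markers above the filter were too few for a test, with none called. The endothelial median was 0.030 without miR-126 array A and -0.44 without array B (adjusted p = 0.0411), and the luminal median -0.24 (adjusted p = 0.00891) and -0.043.

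Several lists parted the miR-126 arrays from each other. Hypoxia genes had a median of -0.51 on array A and 0.42 on array B relative to the control mean, and the difference between the arrays, -0.94, lay outside the 95% range of random lists matched on size and expression (-0.14 to 0.18). The difference was -0.92 for NF-kB inflammatory genes, -0.62 for lung metastasis genes, -0.56 for cholesterol synthesis genes and 0.46 for DNA replication genes, each outside the range of its own random lists, and 0.16 for amino acid stress genes, inside theirs. Between the control arrays the NF-kB list differed by -0.101, the hypoxia list by -0.054 and the lung metastasis list by -0.054, which also lay outside the narrower ranges of their random lists there (-0.022 to 0.074, -0.024 to 0.055 and -0.030 to 0.071). Array A also carried more signal on control probe sets for 18S ribosomal RNA, 3.92 to 5.37 times the higher control array, while the 3' to 5' signal ratio of GAPDH, a measure of RNA integrity, was 0.964 on array A, 0.916 on array B and 0.947 and 0.928 on the controls. That of actin was 1.14 on array A and 1.08 on array B, below the 1.20 and 1.17 on the controls.

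**Figure D3:**
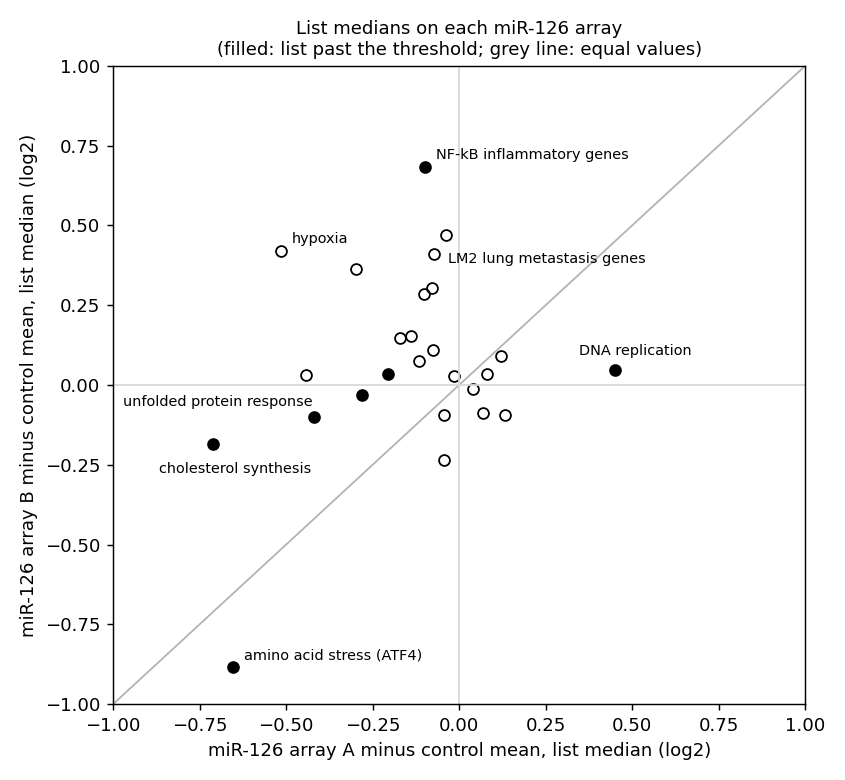
Median log2 level of 26 gene lists on miR-126 array A (horizontal) and array B (vertical), each relative to the mean of the control arrays; filled points are lists past the threshold and the grey line marks equal values. The amino acid stress list lies low on both arrays, at -0.65 and -0.88, while the hypoxia list lies at -0.51 and 0.42.

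The design also sets the comparisons side by side, asking which genes are higher in the metastatic line and lower when miR-126 is over-expressed. Since no gene passed with miR-126, 0 genes did so in both, of 97 higher in LM2 among 9773 genes measured in both tables. At an unadjusted p under 0.05 in both, 65 genes were higher in LM2 and lower with miR-126, of 499 and 487, where 24.9 would be expected (odds ratio 3.14, 95% interval 2.34 to 4.17, Fisher's exact p = 4.38e-13, two-sided, with genes taken as independent). The odds ratio was 0.817 for genes higher in both, 0.88 for genes lower in both and 0.818 for genes lower in LM2 and higher with miR-126. Of the 65 genes, 20 passed in LM2 at the adjusted threshold and 7 belonged to the amino acid stress list. Chosen after their values were seen, PHGDH, PSAT1, SHMT2 and NUPR1 were among them, with IGFBP2, the stress cytokine GDF15 (0.84 in LM2, -2.04 with miR-126) and the integrin chain ITGB4 (1.39 and -1.12). An excess was seen with miR-126 array A as the only miR-126 array but not with array B. These fits take their spread from the controls and do not test the 65 shared genes themselves. With array B as the only miR-126 array the odds ratio was 1.09 (0.878 to 1.34, Fisher's exact p = 0.425), and with array A alone it was 3.05 (2.53 to 3.68). Without control array A or B it was 6.74 or 7.26, on 26 or 30 shared genes, and without LM2 array A 36 genes were shared. Across the 9773 genes, which are not independent replicates, the fold changes were nearly unrelated (Pearson's r -0.0758, Spearman's rho -0.0665), with r at 0.00407 without miR-126 array A.

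**Figure D4:**
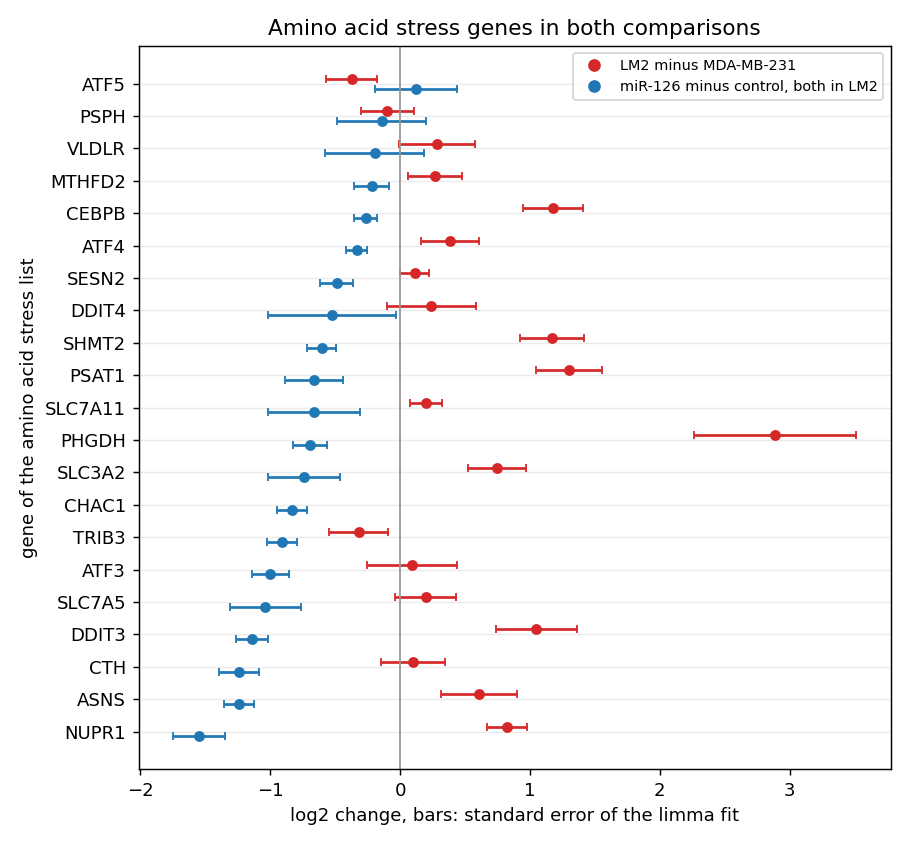
Log2 change of the 21 amino acid stress genes in LM2 against MDA-MB-231 (red) and in miR-126 against control cells (blue), with bars of 1 standard error from the limma fit; CHAC1 lay below the filter on the Illumina arrays. NUPR1 lies at 0.82 and -1.55, and 20 of the 21 blue points lie below 0.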

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

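The scaling test in this part was chosen after the result was seen, and so was cyclic loess, 1 of its scalings.

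Control probe sets, which the comparisons did not use, carried more ribosomal RNA signal on miR-126 array A than on the control arrays. The probe sets for the 3' end, the 5' end and the middle of 18S ribosomal RNA stood at 3.92, 5.37 and 4.58 times the higher control array, and the 5' probe set of a further control sequence at 2.49 times. On array B the same sets stood at 1.09, 1.14, 1.11 and 1.03 times.

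The miR-126 arrays also lay far apart. The scaling of the arrays does not account for that spread, since the mean difference between the miR-126 arrays was at least 3.27 times that between the controls under each of 3 scalings. Whether the ribosomal RNA on array A, or a difference between the miR-126 cultures or their RNA, contributed was not tested, and both stay open. The design names no such difference and no biological explanation was tested.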

How the results depend on the processing

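Cyclic loess and the assumed log form were chosen after the data were seen; the rest were planned. For LM2 against MDA-MB-231, both counts stayed within 1.5 times the reported ones under quantile normalization, pseudocounts of 1 and 64, either filter, every probe tested, a robust prior and a fold minimum. They were 66 higher and 118 lower with the mean of all probes, 41 and 66 without a variance trend, and 46 to 294 and 40 to 397 with an array left out. With miR-126, counts were 0 under each setting other than the block and the arrays left out, which gave 0 to 2549 higher and 0 to 2321 lower. Lists past the threshold fell to 0 in both comparisons with an estimated correlation, and to 0 in LM2 and 1 with miR-126 under fry; arrays left out gave 9 to 15 lists with miR-126. With a lone array, its spread is assumed to be that of the other group. The estimated correlation over the amino acid stress list with miR-126 was -0.00201, below the preset 0.01. The loss of that list in this setting therefore does not come from correlation between its genes. The estimate was also below 0.01 for the interferon list in LM2, at -0.00492. For the other lists past the threshold it was higher, from 0.0255 (amino acid stress) to 0.396 (MAPK output) in LM2. With miR-126 it ran from 0.0193 (MAPK output) to 0.763 (DNA replication). For these lists correlation between genes may account for the loss, and the camera p at the preset correlation may be too small.

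At the adjusted threshold, genes higher in LM2 and lower with miR-126 numbered 0, and 0 to 55 with an array left out. At an unadjusted p they numbered 65, and 26 to 229 with an array left out, with odds ratios from 1.09 to 7.26. The correlation of fold changes was -0.0512 without a filter and -0.113 to 0.00407 with an array left out. Beyond the smaller number of arrays, the cause of these moves was not tested.

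Named genes kept direction and side of the threshold in 601 of 711 combinations of gene and setting in LM2, where 98 lost their call, 9 gained one and 3 turned sign. With miR-126, 274 of 322 stayed, 39 gained a call and 9 turned sign. With an array left out, LM2 changes ran from -0.12 to 0.55 for MERTK and from -0.20 to 0.27 for SPRED1. With miR-126 they ran from -0.75 to 0.11 for ANGPTL4, -0.25 to 0.017 for EGFL7, -0.64 to 1.14 for MMP1, -0.040 to 1.10 for PTGS2, -0.33 to 0.15 for PTPRN2, -1.49 to 0.54 for SOX4, -0.50 to 0.063 for SPRED1 and -0.56 to 1.44 for VCAM1. TNC stood at -0.072 with the mean of its 3 probe sets, of which 1 lay above the filter.

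Arrays of the same letter deviated together with correlations of 0.128 and 0.0598, which does not show that the letters pair samples. A difference shared by letter is not excluded on the Illumina arrays. There array A lay above array B over hypoxia genes in both MDA-MB-231 (0.56) and LM2 (0.39). With the letter as a replicate block, 209 genes were higher and 411 lower in LM2, 7 higher and 13 lower with miR-126, 12 lists passed with miR-126 and 3 genes overlapped. The test of miR-126 sites was not run. Signal over background limits dim genes on the Illumina arrays, whose folds are understated.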

Other observations

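The synthetase test in this part was fixed before its values were seen, without AARS1 and WARS1, whose values had been. The deposited scale and the arrays left out were planned, but their use to test explanations was chosen after the results were seen. Cyclic loess, the comparisons between arrays of a group, the overlaps without the amino acid stress genes and in the other directions, and the tests of the LM2 genes as sets were also chosen then.

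ID3, which had the largest change among the genes of smallest p with miR-126, stood at opposite signs in the comparisons. Its log2 change was -2.26 in LM2 against MDA-MB-231 (adjusted p = 0.00989, a call lost without LM2 array A and under 2 other variance priors) and 2.44 with miR-126 (adjusted p = 0.446). ID1, chosen after its values were seen, had changes of -0.43 (adjusted p = 0.577) and 1.01 (adjusted p = 0.486). ID genes are known to respond to BMP and TGF-beta signalling, and the TGF-beta list as a whole did not pass in either comparison with all arrays. With miR-126 its median was 0.36 without array A and -0.30 without array B. Adjusted over the list alone, 3 of its genes were higher and 1 lower with miR-126. Genes that parted miR-126 array A from array B most, ranked after their values were seen, included the aldolase ALDOC (-2.61 log2, A minus B), the immediate early genes EGR1 (-2.51) and NR4A2 (-2.32), and the inflammatory cytokines CXCL8 (-2.18) and IL6 (-1.94). MMP1 (1.78) lay the other way.

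The MDA-MB-231 arrays also differed by gene group. Array A exceeded array B by a median of 0.56 log2 over hypoxia genes, 0.52 over TGF-beta response genes, 0.35 over glycolysis genes, 0.24 over unfolded protein response genes and 0.13 over secreted angiogenic factors. It also did so over lists that passed in LM2, by 0.39 for epithelial, 0.23 for antigen presentation, 0.22 for amino acid stress and 0.12 for matrix genes. Array A minus array B was -0.39 for cholesterol synthesis genes and -0.35 for mitosis genes. Each of these medians lay outside the 95% range of random lists. LM2 array A also exceeded array B outside that range over hypoxia (0.39), TGF-beta response (0.34), matrix (0.32) and glycolysis genes (0.31). Over the other lists named here the difference between the LM2 arrays lay inside it.

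Amino acid stress genes stood lower with miR-126. Scaling of the arrays does not account for this, since the list's median was -0.66 or lower under each of 3 scalings. Nor does 1 array, since the median nearer to the controls was -0.65, and the difference that parts the miR-126 arrays was 0.16 log2 over this list. A state shared by both control cultures cannot be told apart from miR-126, since the controls differed by -0.00792 over the list and may share a culture. Lower activity of ATF4 is a candidate explanation. With miR-126, 9 tRNA synthetases known as its targets had a median of -0.20 against 0.09 for 6 others (difference -0.291, permutation p = 0.17 over gene labels, adjusted p = 0.17 over 2 tests). In LM2, 9 against 7 synthetases, not all the same genes, differed by 0.371 (permutation p = 0.04, adjusted p = 0.08). This explanation stays open.

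Genes higher in LM2 were over-represented among those lower with miR-126. The genes of the fixed amino acid stress list alone do not account for it, since the odds ratio without them was 2.85 (2.09 to 3.83). The tRNA synthetase genes AARS1 and WARS1, outside that list, were among the shared genes. The amino acid stress response as a whole is therefore not excluded. Calls gathered in bright genes could raise the overlap of genes higher in both, and its odds ratio was 0.817. That overlap uses genes that stood higher with miR-126, whose brightness may differ from that of genes that stood lower. No overlap matched on brightness was run, so this explanation is not excluded. The excess may also come from whatever sets miR-126 array A apart, since with array B as the only miR-126 array the odds ratio was 1.09. That fit calls another set of genes, and the shared genes were not themselves tested on array B. Their selection at an unadjusted p under 0.05 used both miR-126 arrays and favours genes that stand lower on each. The odds ratio of 1.09 therefore does not place the shared genes on array A alone. As a set, the 97 genes called higher in LM2 had a median change of -0.13 with miR-126 (camera p = 0.00113, and p = 0.485 with an estimated correlation). The 154 genes called lower in LM2 had a median change of -0.00778 with miR-126 (camera p = 0.222, and p = 0.609 with an estimated correlation).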
